A study of Mus musculus with 4 samples.

How the data were processed

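Primary chondrocytes of C57Bl/6 mice were grown ex vivo as micromass cultures, dense spots of cells in which chondrocytes lay down cartilage matrix. Per the labels, a culture transduced with Cre recombinase adenovirus was the Hdac3 knockout and a culture transduced with GFP adenovirus was the control. H3K27ac, the acetylation of histone H3 that marks active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in 1 library of each culture. The series also names 2 input libraries, which were not analysed here. The RNA-seq data named in the series' design were not used here.

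Each H3K27ac library had 1 deposited peak list, so the authors called peaks per library. The submitters' processing notes name bcl2fastq 1.8.4, BWA, Picard, SICER and the mouse build mm10. The deposited lists carry the name and the column order of MACS2 peak output, and the MACS2 version, its settings and the control library behind each list are not given in the sources used here. Each row of the deposited lists gives a peak's position, a score, a fold enrichment, 2 significance values and the summit. In the deposited lists the score was the integer part of 10 times the −log10 q-value in every row. The deposited fold enrichment is a ratio at the summit of observed to expected fragment pileup, with 1 added to both. The deposited −log10 p-value and −log10 q-value refer to the same position. The fold, score and significance of a peak are the authors' values and were used here only to describe, rank or filter peaks within their own list.

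The fold and the −log10 p-value of each peak were solved together for the number of fragments at the summit (the summit pileup) and the expected pileup, with a Poisson upper tail. All peaks, 100% in both lists, gave a whole-number pileup within a tolerance of 0.001. The most frequent expected pileup, taken as the genome background, was 1.01 in the Cre library and 0.949 in the GFP library, a ratio of 1.06. This gives the relative depth of the libraries after the authors' scaling; total read numbers are not given in the sources used here. Pileups reached from 7 to 63 fragments in the Cre library and from 7 to 58 in the GFP library. Counts of this size leave wide counting error at a single peak, and a peak missing from a list can be a region just under the caller's threshold.

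Positions are 1-based mm10 coordinates. Genes came from a RefSeq gene table of GRCm38.p6, whose chromosome coordinates are those of mm10, with 21887 protein-coding genes. The table used here holds gene starts and ends without strand, transcripts or exons. The planned windows of 1 kb around a transcription start were therefore replaced by windows of 1 kb around either annotated end of a gene, called gene boundaries here. These windows take in the 3′ end as well as the promoter. Planned classes for exons and introns were reduced to gene boundary, gene interior and intergenic sequence, assigned by the summit. Planned motif counts were not run, because no genome sequence was used here.

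Peaks overlapped when they shared at least 1 bp. Chance overlap came from 100 shuffles of peak positions within chromosomes, starting 3000000 bp from the chromosome start. A peak was called strong when it had no overlap, no peak of the other list within 1 kb, and a fold in the upper 50% of its own list. A gene's neighbourhood was the gene with 10 kb on each side, and a list's covered length was counted once where neighbourhoods of its members overlapped. Peaks more than 1 kb from a gene boundary were stitched within 12.5 kb into domains, which were ranked by peak-covered length within each library, and the top 200 were compared. Shares carry exact Clopper-Pearson 95% intervals. Nearby peaks and fragments from one amplified library are not independent, so intervals cover counting error only.

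For 24 gene lists with 494 entries, the Cre share of the covered length was set against 10000 random gene lists of the same size, matched in 5 bins of total covered length. The number of members with a boundary peak in the Cre list alone minus those in the GFP list alone was set against random lists matched in 5 bins of fold percentile. Random lists summed their genes one by one. A percentile needed at least 3 members with peaks, and describes these 2 libraries. Mx1, Mx2 and Ankh had no protein-coding match in the table. With 1 library per group there was no replicate check and no p-value across genes.

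The gene lists, the settings and the rule for named genes were fixed before the data were examined. The rule named Hdac3 and 12 anchors, the 10 genes per library with the highest-fold boundary peak absent from the other list, and up to 4 one-library and 2 shared boundary members per list. It also named the genes nearest to the 10 one-library distal peaks of highest fold and to the 10 largest domains of each library. Not every gene that the rule names is reported here. List members named for their neighbourhood alone were chosen after their values were seen. Alternatives covered the peak threshold, list length, sex chromosomes, merging of peaks, the overlap definition, the window sizes, the stitching and the definition of strong peaks. Others, chosen after seeing the data, counted peaks nearest to list members, left out the member of largest difference, kept summits of at least 15 fragments, or stitched both libraries together.

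The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data for the comparison of the Cre with the GFP library. The solver recovered 100% of 4856 simulated pileups. The overlap step found 59.9% of 12873 simulated peaks overlapping, where 59.8% had been left in place. Among 100 simulated lists of 15 genes without a difference, 6% lay outside the 2.5 to 97.5 percentiles. These genes were drawn at random, on 2 random subsets of the GFP peaks. A share near this is given by the construction, so it checks the computation and not the percentiles of lists of related genes. In 100 further lists, each gene lost its whole control cover with a probability of 60%, while the random lists stayed unchanged. Of these lists, 90% lay above the 97.5 percentile. Partial losses within a gene were not simulated. These steps drew on 21887 genes.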

Results

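H3K27ac was compared between Hdac3-deleted (Cre) and control (GFP) primary mouse chondrocyte micromass cultures, with 1 library for each. HDAC3 is a histone deacetylase that works in the NCoR and SMRT corepressor complexes. The series set out to relate this mark to genes whose expression differs in Hdac3-deficient chondrocytes. The Cre list held 13130 peaks covering 3264813 bp and the GFP list held 12873 peaks covering 3236648 bp. Peaks were narrow, with a median width of 194 bp in the Cre list and 198 bp in the GFP list. Median summit pileup was 12 fragments in both libraries, and median fold enrichment, as the authors' caller gave it, was 5.98 and 6.16. There were no replicates, so every difference described here is a difference between 2 libraries.

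Hdac3 itself (chromosome 18, 37936971 to 37955015) had no peak in its neighbourhood in either library. An acetylation profile does not measure the deletion, so the peak lists neither check nor contradict the labels. Mmp13, the main collagenase of cartilage, Il6, an inflammatory cytokine, and Col10a1, the collagen of hypertrophic cartilage, also had no peak in either list. Mmp3, the stromelysin gene, had 1 Cre peak at 7445311 to 7445521 on chromosome 9, its summit 389 bp below the lower gene end, with fold 6.18 and a pileup of 13. The GFP list had none there. Saa3, an acute-phase gene, had 1 Cre peak of 262 bp and no GFP peak, and Phlpp1, an Akt phosphatase, had 1 Cre peak of 148 bp and no GFP peak. Socs3, a feedback inhibitor of cytokine receptors, had 1 GFP peak of 144 bp and no Cre peak. Each of these calls is a single peak, whose presence in a list depends on the caller's threshold.

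Col2a1, Acan, Sox9 and Runx2 had peaks in both cultures. Col2a1, the type II collagen gene (chromosome 15, 97975602 to 98004724), had 3 Cre and 6 GFP peaks covering 976 and 1909 bp, and its boundary pileup was 14 in the Cre and 20 in the GFP library. Acan, encoding aggrecan, had 7 Cre and 10 GFP peaks covering 2798 and 3839 bp. Sox9, the chondrocyte master regulator, had 7 Cre and 3 GFP peaks covering 1463 and 1183 bp, with boundary pileups of 15 and 17. Runx2, which drives hypertrophy, had 3 Cre and 5 GFP peaks, and its boundary peak was called in the GFP list alone (fold 5.97). Timp1, a metalloproteinase inhibitor, had 2 GFP peaks covering 397 bp and no Cre peak.

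The strongest acetylated sites were shared between the cultures and the weak ones mostly were not. All 110 Cre peaks with 30 or more fragments at the summit overlapped a GFP peak, which allows a share down to 96.7% by the exact 95% interval. Of 1840 Cre peaks with 7 to 9 fragments, 18.5% (16.8 to 20.4) did so. For GFP peaks the shares were 98.3% (94.2 to 99.8) of 121 and 22.2% (20.4 to 23.999) of 2120. Over whole lists, 5345 Cre peaks (40.7%, 39.9 to 41.6) and 5333 GFP peaks (41.4%, 40.6 to 42.3) overlapped a peak of the other library, against at most 0.404% and 0.388% in shuffles. These shares depended on the definition: 64.8% and 67.4% had a peak of the other library within 1 kb, and 21.8% and 22.2% overlapped over at least 50% of both peaks. Strong one-library peaks numbered 1980 in the Cre list and 1803 in the GFP list, and 297 and 298 when a −log10 q-value of at least 10 was required.

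**Figure D1:**
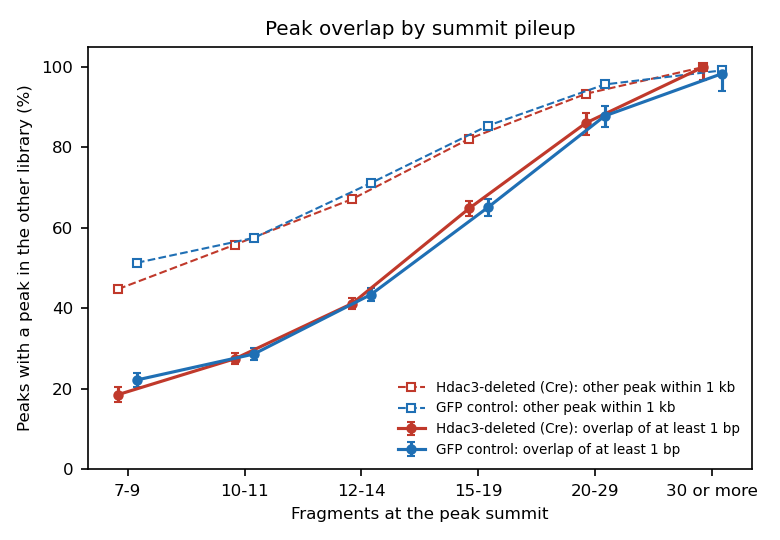
Share of peaks (%, vertical axis) with a peak in the other library, against the number of fragments at the summit (horizontal axis), for the Cre (red) and GFP (blue) lists; filled points are overlaps of at least 1 bp with exact 95% intervals and open squares count any peak within 1 kb. The overlap share of Cre peaks goes from 18.5% at 7 to 9 fragments to 100% at 30 or more.

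Peaks of both libraries lay mostly inside genes. Gene boundaries held 25.5% (24.7 to 26.2) of Cre and 26.8% (26.0 to 27.5) of GFP peaks, gene interiors 52.8% and 54.0%, and intergenic sequence 21.7% (21.0 to 22.4) and 19.3% (18.6 to 20.004). Overlapping peaks were at a boundary in 32.0% (30.8 to 33.3) of the Cre list, against 21.0% (20.1 to 21.9) of its one-library peaks. The GFP list gave 31.5% (30.2 to 32.7) and 23.4% (22.5 to 24.4). Of 21887 protein-coding genes, 2026 had a boundary peak in both libraries, 936 in the Cre list alone, 1044 in the GFP list alone and 17881 in neither.

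The boundary peaks of highest fold found in the Cre list alone were at Cdkn2aip (fold 12.4, pileup 24, chromosome 8, 47714355 to 47714728), Thap7 (fold 11.95), Sh3gl1, an endophilin gene (fold 11.5), Zfp868 (fold 10.96) and Cep20 (fold 10.9). Nrbf2, an autophagy gene, Cdv3, Clcn3, a chloride transporter gene, Ppp2r5b, a phosphatase subunit gene, and Sephs1, of selenium metabolism, followed with folds from 10.5 to 9.96. In the GFP list alone the first was Sec23b, of the secretory vesicle coat (fold 14.4, pileup 27, chromosome 2, 144555908 to 144556124). Pelo, a ribosome rescue factor, had fold 13.9, Commd6 fold 13.3 and Cmss1 fold 12.3. Yars2, a mitochondrial tRNA synthetase, Nptn, Pik3r2, a phosphoinositide kinase subunit, Clk1, a splicing kinase, Fanci, of DNA repair, and Herc4 had folds from 11.3 to 10.3. Each fold ranks a peak within its own list.

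Among distal one-library peaks of highest fold, the Cre list had one whose edge lay 1046 bp from Junb, an AP-1 transcription factor gene (chromosome 8, 84979795 to 84979998, fold 11.5, pileup 22). The others in the Cre list were inside Spidr (fold 11.7, pileup 24), Kcnk2, Arhgef3, Npas3 and Slc24a3, or nearest to Setd4, Epp13, Itga11, an integrin gene, and H1f2, a linker histone gene. Setd4 lay 343926 bp from the edge of its peak and Itga11 50598 bp, so nearest genes are positions and not assigned targets. The highest GFP peak lay 9661 bp from Igdcc3 (chromosome 9, 65196693 to 65196913, fold 16.9, pileup 32). Further GFP peaks were inside Tsc22d4 (fold 12.8), Aff3 (fold 12.3), Usp54, Mtmr2, Dnm3 and Phactr2, or nearest to Prl5a1, Ddr1, a collagen receptor gene, and Fam180a.

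The JAK-STAT, NF-κB, interferon and AP-1 gene lists held more peak-covered length in the Cre library than in the GFP library. JAK-STAT genes, which carry signals of the IL-6 family, had 37 Cre and 23 GFP peaks covering 9625 and 5034 bp, a Cre share of 65.7%. Covered length was greater in the Cre library for 11 members and in the GFP library for 1, Socs3; neighbouring members can share peaks, as Stat5a and Stat5b do in part. Bcl3, a nuclear IκB protein that the fixed list counts with these genes, had 8 Cre peaks and 1 GFP peak (2358 and 267 bp). Its boundary peaks were in the Cre list alone. It was the member of largest difference, and without Bcl3 the list was within the central 95% of random lists (percentile 95.1). Osmr, the oncostatin M receptor gene, had boundary peaks in both lists and covered lengths of 636 and 144 bp. Il6st, the shared receptor subunit gp130, covered 1020 and 315 bp, and Stat3 558 and 261 bp. Stat2 had a boundary peak in the Cre list alone (fold 5.40) and Stat6 in the GFP list alone (fold 5.64).

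NF-κB genes, which mediate inflammatory signals, had 31 Cre and 17 GFP peaks covering 8358 and 4217 bp, a Cre share of 66.5%. Covered length was greater in the Cre library for 5 members and in the GFP library for 4. Traf2, a receptor adaptor gene, had 12 and 5 peaks (3462 and 953 bp), and Nfkb1 had 10 and 3 (2135 and 558 bp). Nfkbia, the IκBα gene, had a boundary peak in the Cre list alone (fold 5.08), while Rel (fold 6.16) and Chuk (fold 5.01) had one in the GFP list alone. Nfkbiz and Birc2 had boundary peaks in both. Interferon response genes had 8 Cre peaks and 1 GFP peak covering 1754 and 144 bp, a Cre share of 92.4%. These peaks lay around 4 of the 18 members in the gene table, and the other members had no peak in either library. The transcription factors Irf3 (fold 7.47) and Irf9 (fold 6.97) and the gene Ifi44 (fold 5.98) had boundary peaks in the Cre list alone, and no member had one in the GFP list alone. AP-1 and immediate-early genes had 40 and 31 peaks covering 12731 and 7557 bp, a Cre share of 62.8%, with 9 members greater in the Cre and 5 in the GFP library. Junb had 8 Cre peaks covering 2428 bp and no GFP peak, Jun had 1 Cre boundary peak (fold 4.98) and no GFP peak, and Fosl2 covered 3825 and 2103 bp. Atf4 and Ier3 had boundary peaks in both.

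These 4 lists lay in the top 2.5% of matched random lists, at percentile 99.5 for JAK-STAT, 98.8 for NF-κB, 99.9 for interferon and 97.9 for AP-1. Of 21 lists with a percentile, 4 lay in the top 2.5% and 2 in the bottom 2.5%, where chance gives 1.05 in both together. Mean folds, which describe each separately called list, were 6.52 and 6.19 for JAK-STAT, 6.29 and 6.06 for NF-κB, 5.94 and 6.67 for interferon, and 6.90 and 6.31 for AP-1. The Cre share of peak numbers was 61.7% (48.2 to 73.9) for JAK-STAT, 64.6% (49.5 to 77.8) for NF-κB, 88.9% (51.8 to 99.7) for interferon and 56.3% (44.0 to 68.1) for AP-1. Without the member of largest difference, the Cre share of covered length was 60.4% at percentile 95.1 for JAK-STAT (without Bcl3), 60% at 91.9 for NF-κB (without Traf2), 86.5% at 97.6 for interferon (without Irf3) and 57.7% at 88.6 for AP-1 (without Junb). With 50 kb on each side of the genes, the interferon share was 58.5% at percentile 89.3 and the NF-κB share 55.2% at 89.15, and among the top 5000 peaks the interferon share was 74.9% at 82.85, on 2 Cre peaks and 1 GFP peak. JAK-STAT was at 92.7 and AP-1 at 83.1 with the gene body alone, JAK-STAT at 75.2 with a −log10 q-value of at least 10 and at 96.8 with summits of at least 15 fragments, and AP-1 at 94.4 with peaks within 500 bp merged and at 97.05 with only the peaks nearest to a member.

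Cartilage matrix genes held less acetylated length in the Hdac3-deleted culture. The list had 163 Cre and 198 GFP peaks covering 47833 and 63557 bp, a Cre share of 42.9% at percentile 1.95, with mean folds of 6.13 and 6.61. Covered length was greater in the GFP library for 17 members and in the Cre library for 4. Matn3, encoding matrilin-3, had 5 Cre and 12 GFP peaks (984 and 3769 bp), Col27a1 2 and 10 (294 and 1965 bp), and Hapln1, the link protein gene, 5 and 8 (1347 and 3394 bp). Col9a1, with the longest acetylated cover of the list, had 43 and 51 peaks over 10955 and 14443 bp. The exceptions were Comp (10 and 5 peaks, 2010 and 1214 bp), Epyc (6 and 2 peaks, 1391 and 288 bp), Matn2 and Cnmd. Boundary peaks were called in both libraries at 15 members, among them Col11a1 and Fmod, in the GFP list alone at Col9a2 (fold 8.21) and Matn3 (fold 3.95), and in the Cre list alone at Vit (fold 4.30). The Cre share of peak numbers, 45.2% (39.9 to 50.4), took in an even split. The percentile ranged from 0.93 to 7.76 over 11 alternatives and stayed under 2.5 in 5 of them. The alternative without chromosomes X and Y, counted among these 5, left the list's peaks unchanged.

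**Figure D2:**
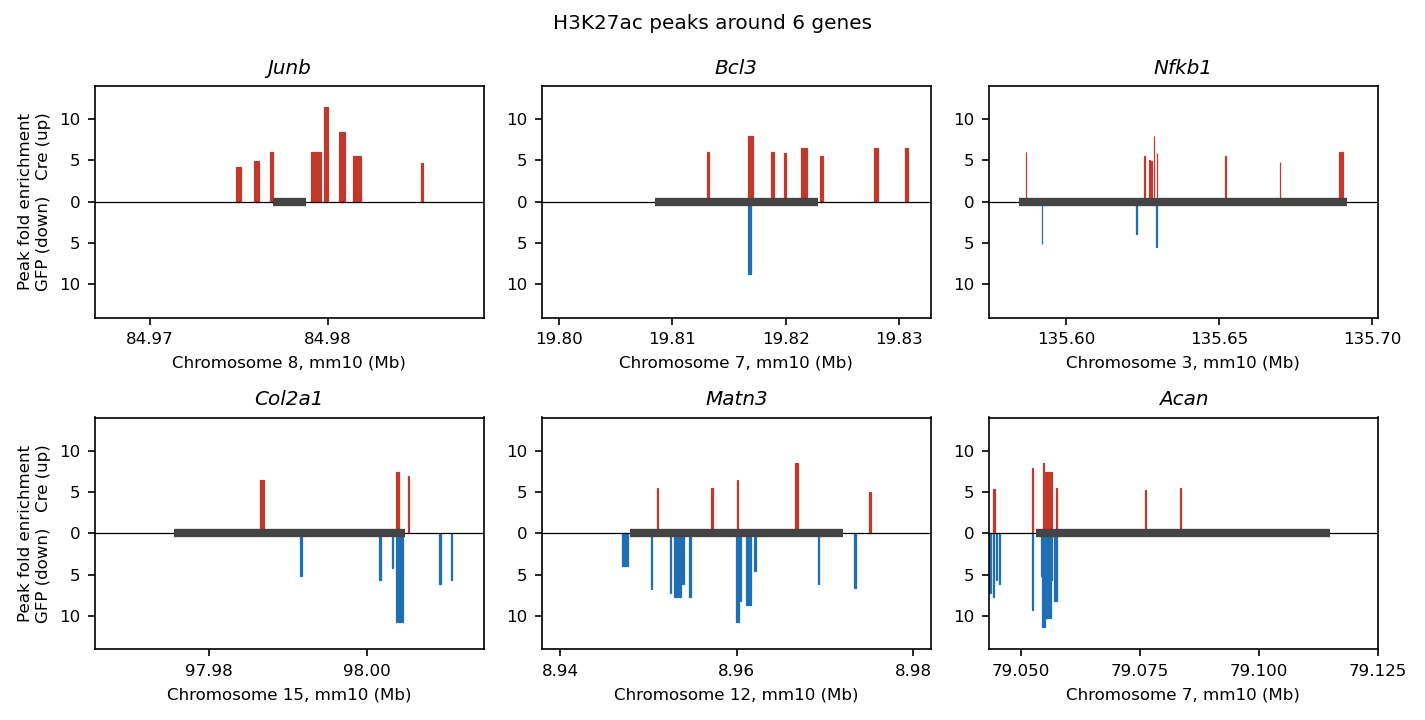
Peaks of the Cre (red, upward) and GFP (blue, downward) lists within 10 kb of 6 genes, by position (Mb, mm10, horizontal axes) and the authors' fold enrichment (vertical axes); the grey bar is the annotated gene. Junb has 8 Cre peaks and no GFP peak, and Matn3 has 5 Cre and 12 GFP peaks.

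Chondrocyte transcription factor genes did not stand apart as a group. They had 246 Cre and 265 GFP peaks covering 77729 and 81103 bp, a Cre share of 48.9% at percentile 43.2 (52.6% at 76.6 without Zbtb20). Zbtb20, a zinc finger repressor gene, had 48 Cre and 83 GFP peaks (13463 and 23147 bp), whereas Hif1a, the hypoxia factor gene, had 13 and 8 (6506 and 3628 bp) and Trps1 40 and 28 (16915 and 14482 bp). Foxc1 and Sox9 had boundary peaks in both libraries and Nfib in the Cre list alone (fold 4.98). Hypertrophy and mineralization genes had 32 and 31 peaks, a Cre share of 49.4% at percentile 50.1 (25.5% at 12.8 with a −log10 q-value of at least 10). In that list Vegfa had a boundary peak in the Cre list alone (fold 4.03), and Sparc, the osteonectin gene, had boundary peaks in both.

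Deacetylase and corepressor genes, the group to which Hdac3 belongs, had 11 Cre and 20 GFP peaks covering 1873 and 3674 bp. The Cre share of 33.8% lay at percentile 4.01, with mean folds of 6.495 and 5.905. The share was 37.3% at 17 with a −log10 q-value of at least 5 and 44.8% at 28.1 with 50 kb on each side. It was 44.3% at 26.35 with summits of at least 15 fragments and 29.9% at 3.06 with only the peaks nearest to a member. At a −log10 q-value of at least 10 it turned to 100%, on 2 Cre peaks and no GFP peak. Hdac2 (fold 7.18), Hdac10 (fold 6.67), Tbl1x (fold 6.67) and Tbl1xr1 (fold 5.13) had boundary peaks in the GFP list alone. No member had one in the Cre list alone, a difference at percentile 2.86. That percentile was 11.6 with a −log10 q-value of at least 5, 19.4 with summits of at least 15 fragments and 2.45 with a boundary window of 500 bp. Ncor1 and Hdac5 had boundary peaks in both. Acetyltransferase and BET reader genes had 32 and 37 peaks, a Cre share of 50.7% at percentile 58.9 (47.4% at 38.7 without Brd2), with boundary peaks in both at Brd2 and Ep300.

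Effector genes of inflammation and matrix breakdown lay within the central 95% of random lists at the main settings. Cytokine, chemokine and acute-phase genes had 8 Cre and 7 GFP peaks, a Cre share of 53.0% at percentile 62.0, with the one boundary call at Csf1 in the GFP list (fold 4.19). The share was 32.6%, on 2 Cre and 4 GFP peaks, both with a −log10 q-value of at least 5 (percentile 17.8) and among the top 5000 peaks (21.1). It was 44.4% at 16.2 with 50 kb on each side of the genes. Without Csf1 it was 63.1% at 84.6, on 7 Cre and 3 GFP peaks. Matrix proteases and inhibitors had 12 and 14 peaks, a Cre share of 47.3% at percentile 42.0 (28.5% at 9.17 among the top 5000 peaks, 54.2% at 66.9 with only the peaks nearest to a member). The proteases Mmp3, Mmp11 (fold 6.97), Mmp14 (fold 5.98) and Ctsk (fold 5.08) had boundary peaks in the Cre list alone, and the inhibitors Timp1 and Timp2 (both fold 6.67) in the GFP list alone. That difference of 4 against 2 lay at percentile 88.2. It was 3 against 4 (percentile 42.8) with a boundary window of 2.5 kb and 1 against 1 (38.4) among the top 5000 peaks. Without chromosomes X and Y it was 4 against 1 (96.1). With summits of at least 15 fragments, no Cre and 3 GFP peaks were left in the list, at percentile 1.77.

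**Figure D3:**
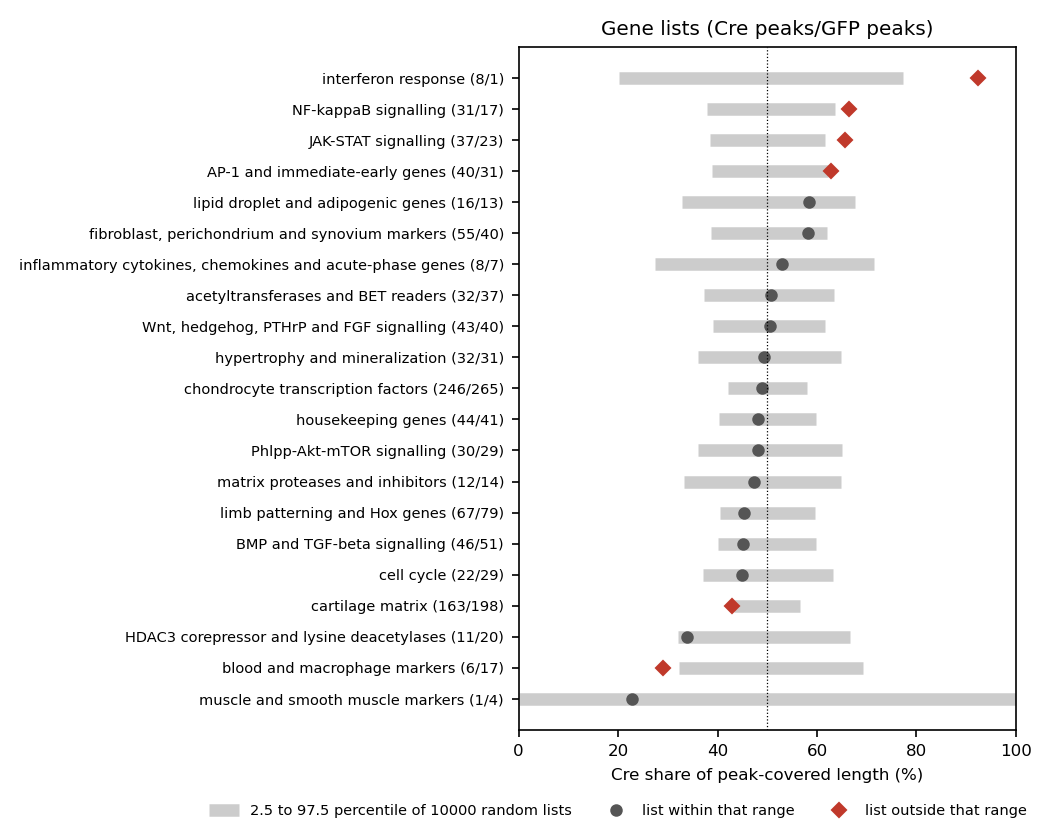
Cre share of peak-covered length (%, horizontal axis) for the 21 gene lists with a percentile, with Cre and GFP peak numbers in brackets; grey bars span the central 95% of 10000 matched random lists, red diamonds are lists outside them and grey circles lists within. Interferon (92.4%), NF-κB (66.5%), JAK-STAT (65.7%) and AP-1 (62.8%) lie above their bars, and cartilage matrix (42.9%) and blood and macrophage markers (29.05%) below.

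The other signalling lists lay within the central 95% of random lists at the main settings. Phlpp, Akt and mTOR genes had 30 Cre and 29 GFP peaks (48.1%, percentile 42.4; 59.2% at 87.2 without Akt2), with Rptor marked at a boundary in the Cre list alone, Mtor in the GFP list alone, and Rps6kb1 and Pik3ca in both. Akt2 covered 2680 bp in the Cre and 5152 bp in the GFP library. BMP and TGF-β genes had 46 and 51 peaks (45.1%, percentile 17.3; 36.8% at 1.77 with a −log10 q-value of at least 5), with Bmpr2 and Smad5 marked in the GFP list alone and Bmpr1a and Bmp5 in both. Wnt, hedgehog, PTHrP and FGF genes had 43 and 40 peaks (50.6%, percentile 58.2; 36.1% at 21.8 with summits of at least 15 fragments), with Fzd1 and Smo marked in the GFP list alone, Fgfr3 in the Cre list alone, and Gli3 and Lrp6 in both. Lipid and adipogenic genes had 16 and 13 peaks (58.4%, percentile 84.8). Among the top 5000 peaks they had 2 and 4 (30.9%, percentile 20.2), and without Cebpb the share was 50.8% at 57.2. In that list Cebpb, an inflammatory and adipogenic transcription factor gene, had 5 Cre peaks and no GFP peak, Scd1 had a boundary peak in the Cre list alone, and Cebpd had boundary peaks in both. Cell cycle genes had 22 and 29 peaks (44.9%, percentile 23.8; 51.9% at 67.95 among the top 5000 peaks), with Cdkn1a marked in the Cre list alone, Pcna in the GFP list alone, and Cdkn1b and Trp53 in both.

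Markers of other cell types that a chondrocyte culture can hold were mostly unmarked. Endothelial genes had no peak in either library, neural genes had 1 Cre and 2 GFP peaks, muscle genes 1 and 4 (22.9%, percentile 15.2; 49.9% at 53.5 with 50 kb on each side) and epithelial and liver genes 5 and 3. Fibroblast, perichondrium and synovium genes were marked in both, with 55 and 40 peaks covering 20226 and 14497 bp (58.2%, percentile 92.4), with mean folds of 6.73 and 6.78. Covered length was greater in the Cre library for 8 members and in the GFP library for 1, and with 50 kb on each side of the genes the share was 61.8% at percentile 98.9. Dcn, the decorin gene, had 17 and 7 peaks over 7637 and 4992 bp, Lum had boundary peaks in both, and Col1a2 had a boundary peak in the GFP list alone (fold 6.67) and no Cre peak. Blood and macrophage genes had 6 and 17 peaks (1627 and 3974 bp), a Cre share of 29.05% at percentile 1.05, with mean folds of 5.45 and 6.24. Of these, 2 Cre and 8 GFP peaks lay around Laptm5, which adjoins the cartilage gene Matn1, and without Laptm5 the percentile was 14.04. With 50 kb on each side of the genes the share was 43.7% at 16.3, and among the top 5000 peaks 18.99% at 2.92. When only peaks nearest to a member were counted, 1 Cre and 3 GFP peaks were left, too few members for a percentile. Fcer1g had the one boundary peak of that list, in the Cre library. Housekeeping genes had 44 and 41 peaks (48.2%, percentile 40.1), with boundary peaks in both at Actb, in the Cre list alone at Eef2 and B2m, and in the GFP list alone at Tuba1b and Tbp. Limb patterning and Hox genes had 67 and 79 peaks (45.3%, percentile 18.3), with Hoxa10 and Hoxa9 marked in both and Hoxa11, Hoxc6 and Meis1 in the GFP list alone.

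Some of the largest acetylated domains of both cultures lay at members of the cartilage and chondrocyte lists, such as Col9a1 and Trps1, and others did not. Whether such genes were enriched among the domains was not tested. First in each library was Wwp2, whose gene holds the cartilage microRNA gene Mir140, with 91 Cre peaks covering 32199 bp (chromosome 8, 107453173 to 107554808) and 94 GFP peaks covering 33157 bp. Trps1, a chondrocyte transcription factor gene, covered 12891 and 12438 bp, Nfix 11557 and 13968 bp, and Col9a1 10711 and 14073 bp. A domain over Fancc and Aopep (chromosome 13, 63240147 to 63303057 in the Cre library) covered 15376 and 14799 bp, and one nearest to Ppara 13786 and 14814 bp. Actn4, Chd2, Xylt1, which starts proteoglycan sugar chains, and Synpo were other leading domains that overlapped a top 200 domain of the other library. Fndc3b covered 14707 bp as the Cre domain of rank 3 and 5913 bp in its best GFP domain, of rank 25; stitched over both libraries together, a choice made after seeing the data, the domain covered 15009 and 10698 bp. Prkch, a protein kinase C gene, covered 12034 bp at Cre rank 6 and 2391 bp at GFP rank 151, and Fgfrl1, an FGF receptor-like gene, 9925 bp at GFP rank 7 and 5206 bp at Cre rank 38; the joint domains covered 12738 and 4081 bp at Prkch and 5635 and 10400 bp at Fgfrl1. Of the top 200 Cre domains, 135 (67.5%, 60.5 to 73.9) overlapped a top 200 GFP domain, against a mean of 0.79 and at most 4 in shuffles.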

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

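No paired analysis was possible because each group had 1 library. A value counted as moved when it left the 95% interval of the main value. That interval was exact for shares, a normal approximation for differences in percentage points, and taken from ranked widths for median widths. Counts moved when they differed by more than 1.5 times, and list shares when they moved beyond the counting error of the share of peaks. By these bounds, 114 main values stayed, 56 moved and 1 reversed, and among secondary values 183 stayed and 56 moved. The alternatives with a summit minimum, with the nearest gene or without a list member were chosen after seeing the data. The cause of the moves was not tested, apart from those that follow from keeping fewer peaks. With a −log10 q-value of at least 5, one-library Cre peaks were at a boundary −13.4 percentage points relative to overlapping ones (main value −11.03), and strong one-library peaks numbered 1242 and 1104. At 10 or more, 43.5% of Cre peaks overlapped, the boundary differences were −19.5 (Cre) and −15.8 (GFP), strong peaks 297 and 298, genes with boundary peaks 500 in both, 300 Cre and 348 GFP, and the domain overlap 47.5%. There, 2 lists lay outside the percentiles, and the Cre shares were 32.2% for cartilage, 77.1% for AP-1 and 0% of 1 blood marker peak; the interferon list held no peak. The top 5000 peaks of each library gave 39.7% overlap of GFP peaks, boundary differences of −14.2 and −11.9 (main GFP value −8.02), 889 and 870 strong peaks, 1077 genes marked in both, 56% domain overlap, and Cre shares of 81.8% for NF-κB and 36.6% for cartilage. Merging within 500 bp gave −14.04 and −10.8 percentage points, 42.4% overlap of GFP peaks and 60.5% domain overlap. Summits of at least 15 fragments gave overlaps of 44.2% (Cre) and 47.6% (GFP), differences of −15.2 and −11.6, 774 and 448 strong peaks, 747 genes in both, 458 Cre and 430 GFP, 56% domain overlap, 3 lists outside, a Cre share of 90.0% for NF-κB and no interferon peak.

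An overlap of 50% of both peaks gave shares of 21.8% and 22.2% and boundary differences of −16.1 and −14.1, and counting peaks within 1 kb gave 64.8% and 67.4% with −8.43 and −3.70. A 500 bp boundary window gave −7.26 and −6.10. The upper 25% by fold left 735 and 689 strong peaks. With 50 kb on each side of genes the interferon share was 58.5% and the NF-κB share 55.2%, both within the range. With the gene body alone, 2 lists lay outside, and the blood marker share reversed to 100% on 1 peak. Without its member of largest difference, 2 lists stayed outside, both close to the cut (interferon at percentile 97.6 and cartilage at 2.47). Of 11 alternatives, the percentile stayed outside in 9 for NF-κB, 7 for JAK-STAT, 7 for AP-1 and 5 for cartilage. Interferon stayed in 7 of the 9 that gave a share and blood markers in 4 of the 7 that gave a percentile. Shares stayed on their side of 50% for JAK-STAT, NF-κB, AP-1 and cartilage in all 11. These counts take in settings that left a list's peaks unchanged and are no separate check. Leaving out chromosomes X and Y did so for each of these lists. Taking the same number of peaks from each library did so for all of them but cartilage, and counting only the nearest peaks did so for NF-κB. Lists within the range at the main settings left it in 3 cases: BMP and TGF-β at a −log10 q-value of at least 5, matrix proteases with summits of at least 15 fragments, and fibroblast genes with 50 kb on each side. Motif counts were not run. Depth limits single calls: the quartiles of the summit pileup were 10 and 14 fragments in both libraries.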

Other observations

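The joint domains, the summit pairs, the chromosome counts and the tests of call threshold, broken regions, library depth, culture make-up, the other loci of a list and neighbouring genes list by list were chosen after the results were seen. When the peaks of both libraries were stitched together into 6995 domains, 3520 held peaks of both, 1811 of the Cre list alone and 1664 of the GFP list alone, the largest of these covering 2575 and 2131 bp. Among these domains, the largest excesses of covered length in the Cre library lay at genes the fixed lists mostly did not cover. A Prkch domain had 37 Cre and 16 GFP peaks (12738 and 4081 bp; Cre share of peaks 69.8%, 55.7 to 81.7), and a neighbouring Prkch domain had 24 and 6. A domain at Dcn, the decorin gene, had 33 and 7 peaks (82.5%, 67.2 to 92.7). Vmp1, whose neighbourhood holds the microRNA gene Mir21a, had 29 and 11 peaks over 9601 and 2993 bp (72.5%, 56.1 to 85.4). Capzb, an actin capping gene, had 20 and 2 peaks (90.9%, 70.8 to 98.9), Babam2 16 and 3, and Ell, of transcription elongation, 27 and 10. These domains were picked as extremes, so their intervals overstate how far they stand out.

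In the other direction, the joint domain with the largest excess of covered length in the GFP library was at Fgfrl1, with 23 Cre and 33 GFP peaks (5635 and 10400 bp). Vgll4, a cofactor of TEAD factors, had 12 and 26 peaks (Cre share 31.6%, 17.5 to 48.7), Boc, a hedgehog coreceptor gene, 18 and 32, and Zfp521, a zinc finger gene, 3 and 15 (16.7%, 3.58 to 41.4). Nrep had 3 and 13 peaks, Serpinh1, the collagen chaperone gene, 10 and 16, and a Zbtb20 domain 8 and 16. The microRNA gene Mir140 was marked alike, with 15 and 16 peaks over 7129 and 7694 bp. At 4427 pairs of summits within 200 bp, the ratio of pileups had a 95% interval that excluded 1 in 0.858%. With no difference at any pair, 95% intervals can exclude 1 in a larger share than this. These pairs therefore do not stand out as a set. The interval lay above 1 in 13 pairs, among them a Vmp1 summit with 36 Cre and 15 GFP fragments and a Dars summit with 31 and 9. It lay below 1 in 25, among them Phf14 with 20 and 46. The named pairs were picked as extremes. Chromosome 10 had 794 Cre and 678 GFP peaks (53.9%, 51.4 to 56.5), the one interval of all chromosomes that excluded an even split. With a 95% interval for each chromosome, 1 such interval can arise by chance.

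Most peaks were called in one library and not in the other. If calls near the threshold were the cause, strong peaks should be shared, and 88.1% of Cre peaks with at least 20 fragments overlapped a GFP peak. If broad acetylated regions were broken into separate narrow peaks, one-library peaks should have neighbours in the other list, and 40.6% of one-library Cre peaks had a GFP peak within 1 kb, against at most 1.17% in 20 shuffles. Both may therefore account for many one-library calls. They leave 43 Cre and 28 GFP peaks of at least 20 fragments with no peak of the other library within 1 kb, and for these a difference between the cultures stays open.

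The JAK-STAT, NF-κB, interferon and AP-1 lists held more covered length in the Cre library. A deeper Cre library would give an excess in all peaks, and the Cre share over all peaks was 50.2%, which argues against it. One locus in each list could carry part of the excess. Without its member of largest difference, 1 of the 4 lists stayed in the top 2.5% of random lists. That was interferon, at percentile 97.6, close to the cut and on 5 Cre peaks and 1 GFP peak. The shares of covered length stayed above 50%, from 57.7% to 86.5%. Peak numbers were then 29 Cre and 22 GFP for JAK-STAT, 19 and 12 for NF-κB, and a near-even 32 and 31 for AP-1. The other loci leaned to the Cre library in 7 of 8 for JAK-STAT (87.5%, 47.3 to 99.7), 4 of 7 for NF-κB, 3 of 3 for interferon and 8 of 13 for AP-1, intervals that all take in an even split. With only the peaks nearest to a member, JAK-STAT was at percentile 99.1 and interferon at 98.5, the latter on 5 Cre peaks and 1 GFP peak. NF-κB was at 98.2, but its 31 Cre and 17 GFP peaks were all nearest to a member, so no peak was removed. AP-1 lay at 97.05 with a nearly equal share, 62.4% against 62.8%. Peaks that lie nearer to other genes thus do not carry the JAK-STAT excess. Nearest position does not show which gene a peak serves, so peaks that act on neighbouring genes stay open for all 4 lists. More fibroblast-like cells in the Cre culture, with the fibroblast list at percentile 92.4 and at 98.9 with 50 kb on each side, the effect of Hdac3 deletion and chance variation between cultures cannot be told apart with 1 library per group.

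The cartilage matrix list held less covered length in the Cre library. Fewer chondrocytes in the Cre culture would be expected to lower chondrocyte transcription factor genes too, and that list lay at percentile 43.2, and at 76.6 without Zbtb20, while the fibroblast list, with 8 members greater in the Cre library and 1 in the GFP library, lay at 92.4; this leaves the question open. Col9a1, the member of largest difference, does not alone carry the lean to the GFP library. Without it the Cre share was 42.9%, and 16 of the 20 other loci (80%, 56.3 to 94.3) had more covered length in the GFP library. These loci were counted after their direction had been seen, and small differences counted as much as large ones. The percentile without Col9a1 was 2.47, too close to 2.5 to decide whether the list stands outside the random lists. A lower acetylation of matrix genes after Hdac3 deletion may be considered as a hypothesis. It was not tested, since 1 culture per group cannot separate the deletion from other differences between the cultures.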
